A study of Homo sapiens with 9 samples.

How the data were processed

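RNA of the human cholangiocarcinoma line HCCC-9810 was measured on Affymetrix arrays in 9 samples, 3 each with si-BAP1, si-MBD5 and control RNA. The labels call the 3 samples of a group biological replicates, so p-values measure the spread between these samples of 1 cell line. The control is called si-Control in the titles and descriptions and control shRNA in the source, characteristics and design text; it is called si-Control here, and which of the 2 was used is not settled. Per the labels, total RNA was extracted with Trizol and 6 ug was made into biotin-labelled cRNA.

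The deposited values are intensity on a linear scale, 1 per probe set and array, and log2 values were computed here from them. Per the submitters' processing notes they were made with MAS5; its version is not given in the sources used here. The deposited intensity had near-identical medians in all arrays (36.9 to 38.2), so the values had been scaled between arrays; that step is not stated, and no further scaling was applied. The table held 49395 probe sets: 102 controls, 44988 with 1 gene symbol, 1832 with several and 2473 with no symbol. Symbols were brought up to date through their gene identifiers with a RefSeq gene table (44961 matched, 27 kept as deposited). No coordinates were used.

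For the main analysis 16 was added to each intensity and log2 taken. Probe sets with 1 symbol were kept if their mean exceeded the 40th percentile of all probe sets (an intensity of 25.5), and each gene was read from its brightest probe set, leaving 12431 of 18132 genes. A linear model with 3 group means was fitted to all 9 arrays (6 residual degrees of freedom) in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and an intensity trend. All p-values called adjusted are Benjamini-Hochberg adjusted over the genes, lists or families of 1 comparison, with a threshold of 0.05. The 3 comparisons were si-BAP1 and si-MBD5 each against si-Control, and si-BAP1 against si-MBD5. Exact permutation tests were used for the target and the quality measures. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

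The 28 gene lists (941 entries, 855 with a probe set on the arrays and 86 without) were tested with camera at a preset correlation of 0.01, for lists with at least 5 tested members. Camera asks whether members moved more in 1 direction than other genes did. The alternative fry asks whether members moved in 1 direction at all, without reference to other genes. A further alternative estimated the correlation between members from the arrays. The target genes, comparisons, model, filter, lists, alternatives and the rule for named genes were chosen before the data were examined. That rule took the targets; the 10 largest rises and falls against control of genes past the threshold with separated arrays; 5 each way between the knockdowns and in both knockdowns; up to 4 members of each list that passed or held at least 3 genes past the threshold; and the BAP1 complex members that passed. Unnamed reading frames and locus symbols were skipped among the largest changes.

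Signal over background sets the precision of arrays. Arrays of the same group correlated at 0.997 to 0.999 (9 pairs) and arrays of different groups at 0.993 to 0.997 (27 pairs), and at most 5.49% of values were identical between any 2 arrays. The median SD within groups was 0.061 log2 (90th percentile 0.105), and the median SE of a fold change 0.051. The procedure was tested on simulated data with 50 changed genes of each size: changes of 0.25 log2 were found in 68%, 66% and 56% of genes in the 3 comparisons, changes of 0.5 log2 in 94%, 98% and 96%, and changes of 0.1 log2 in at most 4%. In the same data 3, 4 and 4 unchanged genes and 0 lists were called. Simulated genes were drawn independently, so the 0 lists do not test camera among correlated genes. The p-value of a permutation of 3 against 3 arrays cannot be under 0.1.

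Agreement between the knockdowns, which share controls, was compared with 100 simulations of no effect. Alternatives tried were constants of 1 and 64, quantile normalization, median centring, no filter, a filter at the 60th percentile, the mean of probe sets, removal of _x_at and _s_at probe sets, the replicate number as block, array weights, no intensity trend, robust variances, only the 2 groups compared, a minimum change of 1 log2 unit, and leaving out each array in turn. Chosen after the data were seen were no added constant, a background covariate, lists without p53 members and the calls of other probe sets of named genes, adjusted over all probe sets above the filter. The 28 lists were not derived from these samples. Probe sets with several symbols or none were counted but not named.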

Results

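The arrays compared HCCC-9810 cholangiocarcinoma cells with si-BAP1, si-MBD5 or control RNA, at n = 3 biological replicates per group. Group values are mean ± SD of the deposited intensity over n = 3 arrays per group. Log2 fold changes, and the folds derived from them, are differences of group means of log2(intensity + 16), with their standard error (SE) and limma adjusted p. The added 16 makes them smaller than the ratio of the printed intensities.

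The arrays did not settle whether MBD5, a methyl-CpG-binding domain protein and the target of 1 knockdown, was lower in si-MBD5 cells, because its signal was near the bottom of the arrays. Its brighter probe set read 6.17 ± 0.056 in si-MBD5 and 7.04 ± 0.13 in control (n = 3 each). The 3 si-MBD5 arrays (6.20, 6.20 and 6.11) lay below the 3 control arrays (7.16, 7.06 and 6.90), with exact permutation p = 0.1, the smallest that 3 against 3 arrays can give. The log2 fold change was -0.055 (SE 0.027, limma unadjusted p = 0.0585, adjusted p = 0.308), and -0.19 without the added constant. For MBD5 the adjustment ran over all 49293 non-control probe sets, without the filter. In si-BAP1 arrays this probe set read 8.66, 7.61 and 6.99, also above the 3 si-MBD5 arrays (limma adjusted p = 0.0657). The mean of this probe set stood at the 11.9th percentile of all probe sets, below the filter. The dimmer MBD5 probe set, at the 0.814th percentile, read 2.34 ± 0.081 against 2.39 ± 0.37 (limma adjusted p = 0.953). BAP1, a nuclear deubiquitinase and the other target, was not analysed here, so the labels of the si-BAP1 arrays were not checked against their target.

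In si-BAP1 cells, 18 of 26 tested p53 targets fell. Lists of replication, mitotic and histone genes were higher at the preset correlation between genes (camera adjusted p = 4.9e-05, 3.2e-05 and 3.8e-04), a call lost with an estimated correlation (adjusted p = 0.196, 0.295 and 0.196). The stress cytokine GDF15 fell from 1631 ± 86 to 648 ± 31 (2.48-fold with 16 added; log2 fold change -1.31, SE 0.053, limma adjusted p = 6.8e-09), and the cyclin-dependent kinase inhibitor CDKN1A from 1650.4 ± 65 to 800.0 ± 11 (2.04-fold with 16 added, log2 fold change -1.03, SE 0.040, limma adjusted p = 6.3e-09). The largest rise was in PPP2R2B, a phosphatase regulatory subunit, from 110.4 ± 15 to 282 ± 16 (2.37-fold with 16 added; log2 fold change 1.24, SE 0.087, limma adjusted p = 5.6e-07). All 5 GDF15 probe sets above the filter were lower, the 2 that changed least among the dimmer ones by log2 0.24 and 0.47. Of 12431 genes tested, 2917 passed an adjusted p of 0.05, 1535 higher and 1382 lower. The majority turned with quantile normalization (1515 higher, 1568 lower) and without si-BAP1 replicate 2 (1173 higher, 1318 lower). Most changes were small: the median size among these genes was 0.22 log2, and 5 genes rose and 5 fell by at least 1 log2 unit. The 3 si-BAP1 arrays lay wholly above or below the 3 control arrays in 37.5% of all genes, where chance gives 10%.

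Other large rises were in SERPINI1, a neuronal serpin (123 ± 10 against 44.7 ± 1.0 in control, log2 1.19), and PXYLP1, a phosphatase of glycosaminoglycan assembly (315 ± 8.9 against 129.5 ± 2.3, log2 1.19, adjusted p = 1.6e-09). MYLK3, a myosin light chain kinase, rose from 94.8 ± 5.8 to 212 ± 4.2, and SV2B, a synaptic vesicle protein, from 79.6 ± 3.1 to 177 ± 3.0. The kinesin KIF26B (log2 0.99), the transporter ABCA13 (0.96), the chloride channel ANO2 (0.92) and the histone genes H2BC5 (0.94) and H2BC11 (0.89) completed the 10 largest rises. Among the largest falls were SERPINE2, an extracellular protease inhibitor (1165 ± 22 against 2560.1 ± 38, log2 -1.13, adjusted p = 5.1e-11), and the ETS factor ELK3 (log2 -1.09). The small GTPase RAB8B (log2 -1.05), the retinol dehydrogenase RDH10 (-0.98), the ferritin receptor SCARA5 (-0.90), the collagen-binding integrin subunit ITGA2 (-0.89) and the death receptor TNFRSF21 (-0.88) also fell. CD2AP, an actin adaptor, fell by log2 0.91, a call that ended without probe sets of the _x_at and _s_at types (adjusted p = 0.224). Of 113 genes named by rule in this comparison, 77 had further probe sets above the filter. In 41 all of these carried the same call, in 14 some, in 22 none, and 0 genes had an opposite call. Among those with none were SCARA5 (0.0077 and -0.020 on its other probe sets), KIF26B (0.043), CDK1, KIF4A, IL6, ACACA, CASP9, FOXK2, PHF19 and ASXL1, all described in this comparison. RAB8B (-0.16 to -0.85), PCGF5 (0.011 to -0.44) and PSMB9 (-0.035 to -0.82) had some.

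Of 26 tested p53 targets, 18 fell and 0 rose (19 and 0 adjusted over the list alone), and 8 did not pass. The median log2 fold change was -0.25 (camera adjusted p = 3.6e-13, and adjusted p = 0.0296 with an estimated correlation). TRIAP1, an apoptosis inhibitor, fell from 1661 ± 59 to 1283 ± 19, and the death receptor FAS from 89.5 ± 4.7 to 42.1 ± 6.0 (log2 -0.87, adjusted p = 1.9e-06). In the NF-kB and cytokine list, 12 of 19 genes fell and 1 rose (13 and 2 adjusted over the list alone; median log2 -0.29; camera adjusted p = 1.0e-05, and adjusted p = 0.0296 with an estimated correlation). They included the early response gene IER3 (log2 -0.79, adjusted p = 8.4e-08), the NF-kB inhibitor NFKBIA (log2 -0.32, adjusted p = 5.0e-05) and the cytokine IL6 (log2 -0.53, adjusted p = 9.4e-05). These 2 lists were the only ones of the 13 called that kept their call with an estimated correlation between genes. In the NF-kB list the estimate was 3.8e-04, below the preset 0.01, yet its camera adjusted p rose from 1.0e-05 to 0.0296. More than the correlation thus differed between these 2 settings, so a lost call does not by itself show correlated members.

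**Figure D1:**
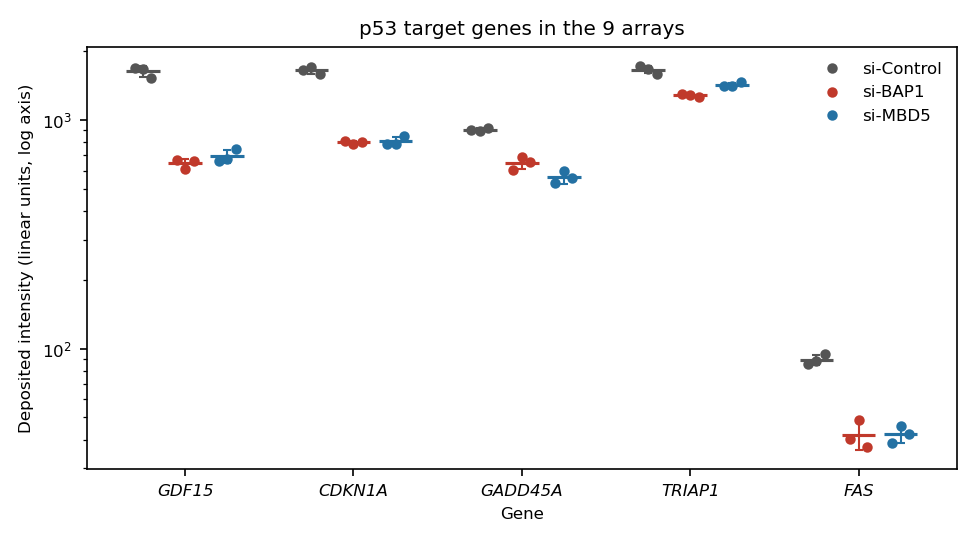
Intensity of 5 p53 targets (log axis) in each array of si-BAP1, si-MBD5 and si-Control cells; dots are single arrays, lines the group means and bars 1 SD (n = 3). GDF15 averaged 648 ± 31, 694 ± 47 and 1631 ± 86, and CDKN1A 800.0 ± 11, 808 ± 39 and 1650.4 ± 65, in that order.

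Other lists were lower in si-BAP1 cells at the preset correlation and with fry (fry adjusted p = 0.0067 or less), and not with an estimated correlation. In antigen presentation, 8 of 19 fell and 1 rose (10 and 1 adjusted over the list alone, median log2 -0.11, camera adjusted p = 1.1e-04, and adjusted p = 0.196 with an estimated correlation). The immunoproteasome subunit PSMB9 (log2 -0.83, adjusted p = 6.1e-08) and the peptide transporter TAP1 (log2 -0.53, adjusted p = 3.0e-06) were among the falls. In ERK output, 11 of 25 fell and 2 rose (11 and 2 adjusted over the list alone, median log2 -0.11, camera adjusted p = 5.0e-04, and adjusted p = 0.196 with an estimated correlation). IER3, the ETS factor ETV5 (log2 -0.74, adjusted p = 2.8e-07) and the receptor EPHA2 (log2 -0.35, adjusted p = 4.8e-05) fell. In ferroptosis and glutathione genes, 12 of 24 fell and 1 rose (12 and 1 adjusted over the list alone, median log2 -0.13, camera adjusted p = 3.4e-04, and adjusted p = 0.295 with an estimated correlation). Among them were GCLC (log2 -0.59, adjusted p = 1.1e-05), the catalytic subunit of glutathione synthesis, and the quinone reductase AIFM2 (log2 -0.32). SLC7A11, the cystine transporter, read 985 ± 31 against 1000.2 ± 30 in control (log2 -0.021, adjusted p = 0.799). In the type I interferon response, 6 of 20 fell and 1 rose (7 and 1 adjusted over the list alone, median log2 -0.10, camera adjusted p = 0.00659, and adjusted p = 0.196 with an estimated correlation). They included IRF1 (log2 -0.45, adjusted p = 1.1e-05) and ISG15 (log2 -0.23, adjusted p = 0.00152). In apoptosis regulators, 9 of 32 fell and 1 rose (9 and 1 adjusted over the list alone, median log2 -0.054, camera adjusted p = 0.00644, and adjusted p = 0.282 with an estimated correlation). Without the 5 members shared with the p53 list the apoptosis call ended (adjusted p = 0.128), and CASP9, an initiator caspase, was its 1 rise (log2 0.40). In glycolysis and hypoxia genes, 9 of 33 fell and 4 rose (12 and 4 adjusted over the list alone, median log2 -0.059, camera adjusted p = 0.0269, and adjusted p = 0.411 with an estimated correlation). The carbonic anhydrase CA12 (log2 -0.48) and the hexokinase HK1 (-0.50) were among the falls. That call ended without si-BAP1 replicate 1 (adjusted p = 0.0647), without si-Control replicate 1 (adjusted p = 0.0544) and with a filter at the 60th percentile (adjusted p = 0.05005).

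The lists that were higher in si-BAP1 cells concerned the cell cycle, DNA repair, histones and sterols. In G1/S and replication genes, 19 of 44 rose and 4 fell (24 and 4 adjusted over the list alone, median log2 0.12, camera adjusted p = 4.9e-05, and adjusted p = 0.196 with an estimated correlation). Examples were the phosphatase CDC25A (log2 0.42, adjusted p = 5.1e-05), the polymerase subunit POLA1 (log2 0.32, adjusted p = 6.8e-05) and the helicase component GINS2 (log2 0.32, adjusted p = 7.5e-05). In G2/M genes, 19 of 42 rose and 2 fell (22 and 2 adjusted over the list alone, median log2 0.12, camera adjusted p = 3.2e-05, and adjusted p = 0.295 with an estimated correlation). Among them were the centromeric histone CENPA (log2 0.40, adjusted p = 2.2e-04), the spindle protein PRC1 (log2 0.22, adjusted p = 1.1e-04) and the kinesin KIF4A (log2 0.27, adjusted p = 6.0e-04). CDK1, the mitotic kinase, went the other way (1292 ± 86 against 2007 ± 55, log2 -0.63), and its call ended without _x_at and _s_at probe sets (adjusted p = 0.945). In homologous recombination and Fanconi anaemia genes, 10 of 27 rose and 0 fell (10 and 0 adjusted over the list alone, median log2 0.14, camera adjusted p = 8.4e-05, and adjusted p = 0.196 with an estimated correlation). They included EXO1 (log2 0.31, adjusted p = 2.0e-04), RAD54B (log2 0.30, adjusted p = 2.2e-04) and BLM (log2 0.31, adjusted p = 6.1e-04). In histone genes, 10 of 19 rose and 1 fell (10 and 1 adjusted over the list alone, median log2 0.10, camera adjusted p = 3.8e-04, and adjusted p = 0.196 with an estimated correlation). H2BC5 rose from 461 ± 41 to 898 ± 30, with H3C4 (log2 0.60, adjusted p = 2.1e-06) and H2BC12 (log2 0.29, adjusted p = 1.1e-04). In cholesterol and fatty acid synthesis, 4 of 25 rose and 1 fell (6 and 1 adjusted over the list alone, median log2 0.10, camera adjusted p = 0.0269, and adjusted p = 0.282 with an estimated correlation). The carboxylase ACACA (log2 0.35, adjusted p = 1.4e-05) was among the rises.

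Among genes of the BAP1 complex and its partners, 2 of 10 rose and 1 fell (3 and 1 adjusted over the list alone, median log2 -0.0055, camera adjusted p = 0.700). The forkhead partner FOXK2 rose from 192 ± 4.6 to 256 ± 9.3 (log2 0.39). UBE2O, a ubiquitin-conjugating enzyme, had log2 0.17 (adjusted p = 0.0402), a call lost without si-Control replicate 2 (adjusted p = 0.177) and in several other settings. ASXL1, the scaffold subunit, had log2 -0.18 on its brightest probe set (adjusted p = 0.00896) and turned to 0.0349 on the mean of its probe sets (adjusted p = 0.489). In Polycomb subunits, 9 of 30 rose and 3 fell (9 and 3 adjusted over the list alone, median log2 0.029, camera adjusted p = 0.207): PCGF5 fell from 341 ± 25 to 181 ± 3.7, while KDM2B (log2 0.47) and PHF19 (0.41) rose.

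Marker lists of other cell types did not pass in si-BAP1 cells: hepatocyte (camera adjusted p = 0.945), fibroblast and endothelial (0.789) and immune (0.772). Cholangiocyte markers (adjusted p = 0.772), epithelial junction and keratin genes (0.354) and mesenchymal genes (0.765) did not pass either. Nor did HOX genes (camera adjusted p = 0.752), the unfolded protein response (0.397), Wnt and Notch targets (0.785), oxidative phosphorylation (0.138), ribosomal proteins (0.789) and heat shock genes (0.752). Targets of YAP and TAZ had 9 of 22 higher and 3 lower (9 and 3 adjusted over the list alone; camera adjusted p = 0.0752), with the matrix proteins CCN2 (log2 0.62) and CCN1 (0.48) among the rises; without the 1 p53 target among them the list passed at the preset correlation (adjusted p = 0.0232), and not with an estimated correlation (adjusted p = 0.421). The median, the mean and the test differed in sign for PR-DUB, mesenchymal, hepatocyte and heat shock lists. The ratio of 3' to 5' ACTB signal, a sign of RNA quality, was 11.1 ± 0.31 in si-BAP1 and 12.2 ± 0.52 in control arrays (exact permutation p = 0.1, the smallest possible). The 3 si-BAP1 arrays (10.8 to 11.4) all lay below the 3 control arrays (11.8 to 12.8). Whether this difference bears on the gene changes was not tested. The GAPDH ratio was 1.08 ± 0.011 and 1.06 ± 0.026 (exact permutation p = 0.3).

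In si-MBD5 cells, 20 of 26 tested p53 targets fell. The list of mitotic genes was higher at the preset correlation (camera adjusted p = 2.6e-13), a call lost with an estimated correlation (adjusted p = 0.176). GDF15 fell from 1631 ± 86 to 694 ± 47 (2.32-fold with 16 added; log2 fold change -1.21, SE 0.053, limma adjusted p = 3.0e-08; 0.25 and 0.52 lower on those 2 dimmer probe sets), CDKN1A to 808 ± 39 (2.02-fold with 16 added; log2 fold change -1.02, SE 0.040, limma adjusted p = 2.2e-08), and FAS from 89.5 ± 4.7 to 42.2 ± 3.6 (log2 -0.86). The largest rise was in the nucleotide receptor P2RY6, from 119 ± 11 to 213 ± 18 (1.70-fold with 16 added; log2 fold change 0.77, SE 0.064, limma adjusted p = 7.1e-06). Of 12431 genes, 2024 passed, 906 higher and 1118 lower, with a median size of 0.21 log2. On the brightest probe sets 2 genes fell and 0 rose by at least 1 log2 unit. Dimmer probe sets of PRSS23 (log2 1.01, limma adjusted p = 4.7e-08) and TPM4 (log2 1.01) did rise by that much. Array values were fully separated in 30.4% of all genes, where chance gives 10%. Without si-Control replicate 2 the count was 1265 (587 higher, 678 lower), and the majority turned without si-MBD5 replicate 1 (734 higher, 713 lower) and with quantile normalization (1107 higher, 1056 lower).

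After P2RY6, the largest rises were in MYLK3 (log2 0.74), GANAB, a glucosidase of the endoplasmic reticulum (783 ± 68 against 467 ± 16, log2 0.72), PPP2R2B (0.70) and the stress granule protein G3BP2 (0.70). The palmitoyltransferase ZDHHC16 (log2 0.69), SERPINI1 (0.65), the syntaxin-binding STXBP6 (0.62), the kinetochore protein ZW10 (0.62) and the annexin ANXA6 (0.59) followed. Falls included the calcium-binding S100A16 (448 ± 16 against 828 ± 26, log2 -0.86, adjusted p = 3.0e-08), RAB8B (log2 -0.92), the carboxypeptidase CPA4 (-0.73) and the splicing regulator PTBP2 (-0.66). SESN1, a stress-induced regulator of growth, fell from 115 ± 7.2 to 61.8 ± 4.3, and GADD45A, a DNA damage response gene, from 908 ± 14 to 561 ± 36. IL6ST, the shared receptor subunit of interleukin-6 family cytokines, read 517 ± 53 against 955 ± 46 (log2 -0.87, adjusted p = 2.7e-06), a call that ended without _x_at and _s_at probe sets (adjusted p = 0.0692). Of the 5 other IL6ST probe sets above the filter (log2 -0.71 to -0.14), 4 carried the same call and 1 did not pass. Of 107 genes named by rule in this comparison, 75 had further probe sets above the filter. In 29 all of these carried the same call, in 23 some, in 23 none, and 0 genes had an opposite call. Among those with none were IRF1, OGT, FOXK2 and ASXL1, while RAB8B (-0.12 to -0.78), G3BP2 (0.11 to 0.26) and STXBP6 (0.052 to 0.43) had some.

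Of the 26 p53 targets, 20 fell and 0 rose (22 and 0 adjusted over the list alone), and 6 did not pass (median log2 -0.29; camera adjusted p = 6.0e-17, and adjusted p = 0.0172 with an estimated correlation). In the NF-kB and cytokine list, 11 of 19 fell and 0 rose (12 and 0 adjusted over the list alone; median log2 -0.18, camera adjusted p = 1.2e-06, and adjusted p = 0.0172 with an estimated correlation). Falls there included IER3 (log2 -0.52, adjusted p = 7.1e-06), NFKBIA (log2 -0.37, adjusted p = 4.5e-05) and the complement component C3 (log2 -0.55, adjusted p = 3.9e-05). As with si-BAP1, these 2 lists alone, of the 11 called, kept their call with an estimated correlation. In G2/M genes, 21 of 42 rose and 0 fell (28 and 0 adjusted over the list alone, median log2 0.14, camera adjusted p = 2.6e-13, and adjusted p = 0.176 with an estimated correlation). Examples were BIRC5 (log2 0.30, adjusted p = 6.5e-05), CENPA (log2 0.42, adjusted p = 3.6e-04) and CDC25C (log2 0.31, adjusted p = 0.00131). In G1/S and replication genes, 8 of 44 rose and 1 fell (8 and 1 adjusted over the list alone, median log2 0.046, camera adjusted p = 0.00988, and adjusted p = 0.380 with an estimated correlation). Among them was the thymidine kinase TK1 (log2 0.23, adjusted p = 9.9e-04). In heat shock genes, 6 of 18 rose and 0 fell (6 and 0 adjusted over the list alone, median log2 0.042, camera adjusted p = 0.0114, and adjusted p = 0.229 with an estimated correlation). They included the chaperones HSP90AA1 (log2 0.34, adjusted p = 2.5e-05) and HSPD1 (log2 0.18, adjusted p = 0.00126). In homologous recombination and Fanconi anaemia genes, 6 of 27 rose and 0 fell (6 and 1 adjusted over the list alone, median log2 0.079, camera adjusted p = 0.0394, and adjusted p = 0.507 with an estimated correlation). The rises included RAD54B (log2 0.20) and BLM (0.23). That call ended without si-Control replicate 1 (adjusted p = 0.168), without si-MBD5 replicate 2 (adjusted p = 0.191) and with fry (adjusted p = 0.0810).

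Lower lists in si-MBD5 cells included ERK output, where 11 of 25 fell and 1 rose (11 and 1 adjusted over the list alone, median log2 -0.092, camera adjusted p = 6.5e-05, and adjusted p = 0.176 with an estimated correlation). The phosphatases DUSP5 (log2 -0.49, adjusted p = 1.1e-04) and DUSP4 (log2 -0.34, adjusted p = 1.0e-04) and the ETS factor ETV5 (log2 -0.47) were among them. In nuclear oxidative phosphorylation genes, 10 of 49 fell and 1 rose (15 and 1 adjusted over the list alone, median log2 -0.056, camera adjusted p = 4.0e-04, and adjusted p = 0.176 with an estimated correlation). Examples were ATP5PD (log2 -0.18, adjusted p = 0.00218) and COX7B (log2 -0.11, adjusted p = 0.00417). In apoptosis regulators, 12 of 32 fell and 1 rose (15 and 1 adjusted over the list alone, median log2 -0.08, camera adjusted p = 0.00250, and adjusted p = 0.274 with an estimated correlation). Without the 5 p53 targets that call ended (adjusted p = 0.09995). In antigen presentation, 8 of 19 fell and 0 rose (8 and 1 adjusted over the list alone, median log2 -0.051, camera adjusted p = 0.00512, and adjusted p = 0.380 with an estimated correlation). Among them were PSMB9 (log2 -0.56, adjusted p = 5.3e-06) and TAP1 (log2 -0.37). In ferroptosis and glutathione genes, 10 of 24 fell and 2 rose (11 and 2 adjusted over the list alone, median log2 -0.11, camera adjusted p = 0.00907, and adjusted p = 0.507 with an estimated correlation), with GCLC (log2 -0.41, adjusted p = 4.5e-04) lower. With a filter at the 60th percentile that call ended (adjusted p = 0.0537). SLC7A11 rose to 1142 ± 70 from 1000.2 ± 30 (log2 0.19, adjusted p = 0.0114).

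Of the BAP1 complex and its partners, 2 of 10 rose and 2 fell (3 and 3 adjusted over the list alone, median log2 0.0071) in si-MBD5 cells (camera adjusted p = 0.974). OGT, the O-GlcNAc transferase, had log2 -0.22 and FOXK2 0.20, and neither passed on the mean of its probe sets (adjusted p = 0.217 and 0.0917). UBE2O had log2 0.18 (adjusted p = 0.0467), lost without si-Control replicate 2 (adjusted p = 0.199) and in several other settings, and ASXL1 -0.23, which turned to 0.000682 on the mean of its probe sets. Polycomb subunits (camera adjusted p = 0.810), HOX genes (0.598) and histones (0.716) did not pass. Nor did hepatocyte (camera adjusted p = 0.885), fibroblast and endothelial (0.526), immune (0.716), cholangiocyte (0.885), epithelial (0.885) and mesenchymal (0.786) markers. The type I interferon response (camera adjusted p = 0.0893), the unfolded protein response (0.0893), YAP and TAZ targets (0.526), Wnt and Notch targets (0.765), sterol synthesis (0.526), glycolysis (0.248) and ribosomal proteins (0.850) did not pass. Among them the interferon regulator IRF1 (log2 -0.42, adjusted p = 4.5e-05) and the hypoxia-induced peptide ADM (log2 -0.33, adjusted p = 2.5e-05) fell. The median, the mean and the test differed in sign for PR-DUB, Wnt and Notch, and mesenchymal lists. Unlike the histone list, a wider family of 36 histone cluster genes, chosen after the data were seen, was called higher (median log2 0.049). In it 3 genes were higher and 0 lower, a share of rises near that of all genes (906 of 12431). The family passed at the preset correlation (camera adjusted p = 0.0454 over 19 families) and not with an estimated correlation (adjusted p = 0.337).

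**Figure D2:**
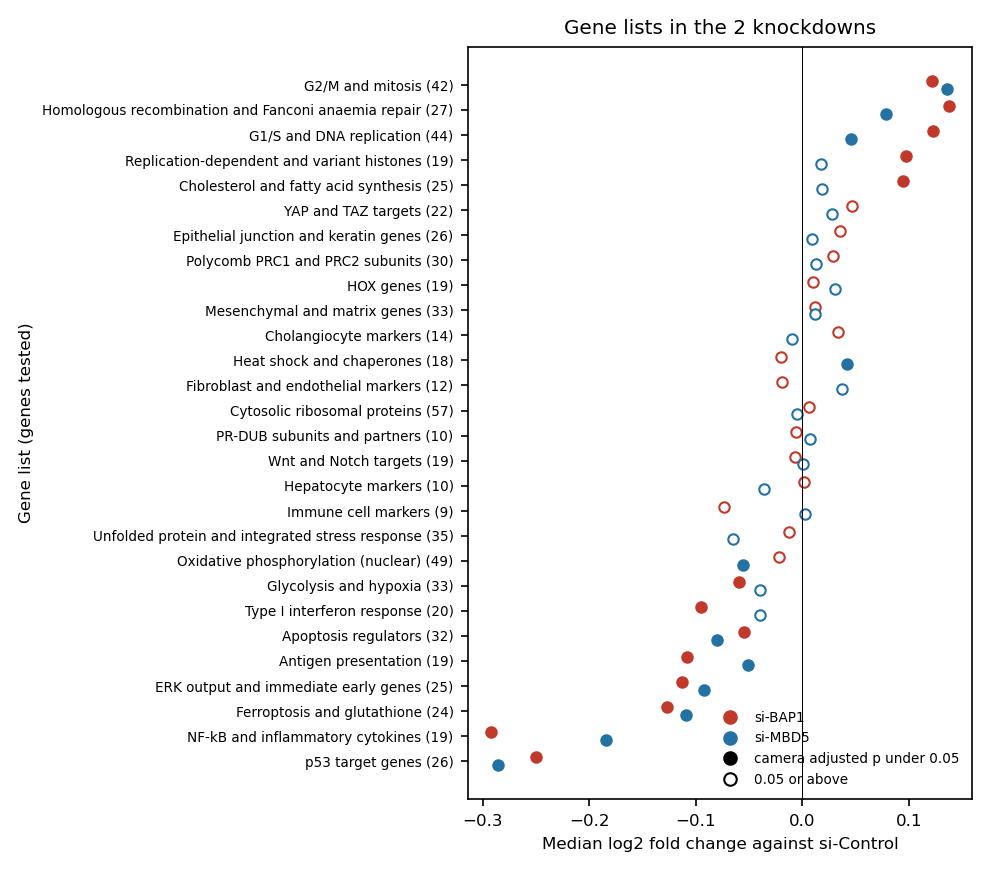
Median log2 fold change of the tested members of each of the 28 gene lists, for si-BAP1 and si-MBD5 against si-Control; filled points have a camera adjusted p under 0.05 at the preset correlation. The p53 targets lie at -0.25 and -0.29.

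Compared directly, si-BAP1 and si-MBD5 cells differed most in DHRS2, a reductase, at 121 ± 4.8 and 50.8 ± 3.2 (2.04-fold with 16 added; log2 fold change 1.03, SE 0.050, limma adjusted p = 2.5e-07). SV2B (log2 0.76), the sterol enzyme MSMO1 (529 ± 46 against 318 ± 19, log2 0.71), the RNA-binding protein QKI (0.69) and MPZL3 (0.68) were also higher in si-BAP1. The phosphatase PTPN11 (153 ± 13 against 277 ± 5.6, log2 -0.80), the actin-binding CORO1C (-0.80), LYSMD2 (-0.77) and SCARA5 (-0.75) were lower. CD2AP had log2 -0.92, a call that ended without _x_at and _s_at probe sets (adjusted p = 0.327). Of 12431 genes, 1239 passed, 715 higher and 524 lower in si-BAP1, and 24.99% were fully separated, where chance gives 10%. With quantile normalization the split turned to 602 higher and 711 lower. Single arrays moved the counts: 755 genes (425 higher, 330 lower) without si-BAP1 replicate 3 and 720 (345 higher, 375 lower) without si-MBD5 replicate 1, 370 higher and 474 lower without si-BAP1 replicate 2, and 339 lower without si-BAP1 replicate 1. Of 69 genes named by rule in this comparison, 52 had further probe sets above the filter. In 16 all of these carried the same call, in 15 some, in 21 none, and 0 genes had an opposite call. Among those with none were SCARA5, MPZL3 (-0.010 on its other probe set), CDK1, DOCK5, H2BC12 and HMMR.

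Of the 28 lists 5 were called between the knockdowns, histone genes with the smallest camera adjusted p: 6 of 19 were higher and 0 lower (8 and 0 adjusted over the list alone, median log2 0.071) in si-BAP1 relative to si-MBD5 (camera adjusted p = 1.6e-04, and adjusted p = 0.475 with an estimated correlation). They included H2BC5 (log2 0.56, adjusted p = 4.3e-05), H3C4 (log2 0.52, adjusted p = 2.5e-05) and H2BC12 (log2 0.41, adjusted p = 2.5e-05). It was the only list of this comparison called with fry (adjusted p = 0.00612). A wider family of 36 histone cluster genes, chosen after the data were seen, had 8 higher and 2 lower. That family did not pass at the preset correlation (camera adjusted p = 0.0613 over 19 families). In homologous recombination and Fanconi anaemia genes, 3 of 27 were higher and 0 lower (3 and 0 adjusted over the list alone, median log2 0.077, camera adjusted p = 0.0203, and adjusted p = 0.540 with an estimated correlation). In YAP and TAZ targets, 4 of 22 were higher and 1 lower (7 and 1 adjusted over the list alone, median log2 0.086, camera adjusted p = 0.0286, and adjusted p = 0.540 with an estimated correlation). The nucleotidase NT5E (log2 0.39) and DOCK5 (0.35) were among the higher genes. In G1/S genes, 7 of 44 were higher and 1 lower (9 and 3 adjusted over the list alone, median log2 0.041, camera adjusted p = 0.0432, and adjusted p = 0.540 with an estimated correlation). Examples were CDC25A (log2 0.40, adjusted p = 2.8e-04) and RRM2 (log2 0.34, adjusted p = 3.0e-04). In antigen presentation, 5 of 19 were lower and 0 higher (5 and 0 adjusted over the list alone, median log2 -0.085, camera adjusted p = 0.0377, and adjusted p = 0.540 with an estimated correlation). Among them was PSMB9 (log2 -0.27, adjusted p = 0.00152). These last 4 calls all ended without si-BAP1 replicate 2 (adjusted p = 0.0502, 0.0838, 0.0855 and 0.0855). Then 2 lists were called in all. Without si-BAP1 replicate 3, 3 lists were called. Without si-MBD5 replicate 3, 3 of the 5 calls ended: YAP and TAZ targets (adjusted p = 0.0522), G1/S (0.0594) and antigen presentation (0.183). With the background covariate G1/S (adjusted p = 0.0523) and antigen presentation (0.0631) ended. A filter at the 60th percentile ended G1/S (adjusted p = 0.119), homologous recombination (0.0558) and antigen presentation (0.0558). G1/S also ended with quantile normalization (adjusted p = 0.0925) and without si-MBD5 replicate 1 (0.0510), and antigen presentation without a filter (0.0771).

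The p53 list did not separate the knockdowns: 1 of 26 genes was higher and 1 lower in si-BAP1 (1 and 1 adjusted over the list alone; camera adjusted p = 0.908). In G2/M genes, 4 of 42 were lower and 0 higher (4 and 0 adjusted over the list alone, median log2 -0.02, camera adjusted p = 0.0645), with BIRC5 (log2 -0.35) and HMMR (-0.25) lower. The largest of these falls, in CDK1 (log2 -0.70), did not pass without _x_at and _s_at probe sets (adjusted p = 0.514). PCGF5 had log2 -0.71 and turned to 0.0532 without those probe sets (adjusted p = 0.546). SLC7A11 was lower in si-BAP1 than in si-MBD5 cells (log2 -0.21, adjusted p = 0.00951). No list of markers of another cell type passed between the knockdowns, with camera adjusted p = 0.992 for hepatocyte, 0.236 for fibroblast and endothelial and 0.236 for immune markers. The median, the mean and the test differed in sign for HOX, Wnt and Notch, mesenchymal and hepatocyte lists. The ACTB ratio of 3' to 5' signal was 11.1 ± 0.31 in si-BAP1 and 12.3 ± 0.72 in si-MBD5 arrays (exact permutation p = 0.1). Every si-BAP1 array lay below every si-MBD5 array (11.6 to 13.0).

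Changes against control ran in the same direction in both knockdowns for most genes called in both. In 687 genes both were higher and in 701 both were lower, where independent lists of these sizes would share 112 and 124. GANAB (log2 0.79 in si-BAP1, 0.72 in si-MBD5), G3BP2 (0.72, 0.70) and P2RY6 (0.69, 0.77) rose in both, and FAS (-0.87, -0.86), ELK3 (-1.09, -0.65) and RAB8B (-1.05, -0.92) fell in both. Of these 1388 genes, 942 changed more in si-BAP1 (medians 0.27 and 0.23 log2), and 258 differed between the knockdowns past the threshold, 226 of them larger in si-BAP1 and 32 larger in si-MBD5. In 24 genes the directions were opposite, where independent lists would share 239. Among them, chosen after their values were seen, were DHRS2 (log2 0.81 and -0.22), PTPN11 (-0.57 and 0.24), the cyclin CCND1 (0.17 and -0.32) and the chaperone HSP90AB1 (-0.30 and 0.13). Without si-Control replicate 2 the number lower in both was 441.

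Both comparisons used the same 3 control arrays, which alone makes their errors correlate. Over 12431 genes Pearson r was 0.712 and Spearman rho 0.651, where simulations of no effect with shared controls gave a mean r of 0.499 (0.476 to 0.522) and rho of 0.467. The covariance was 0.0144 against a simulated mean of 0.00174 (highest 0.00187), a difference of 0.0127. The simulated groups held no effects and gave 0 genes called in both, so they set no scale for the 687 and 701. The 3 control arrays could not be split into parts of at least 2 arrays each, so part of the excess of r over its simulations, and of the shared counts over independent lists, may come from the shared controls.

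**Figure D3:**
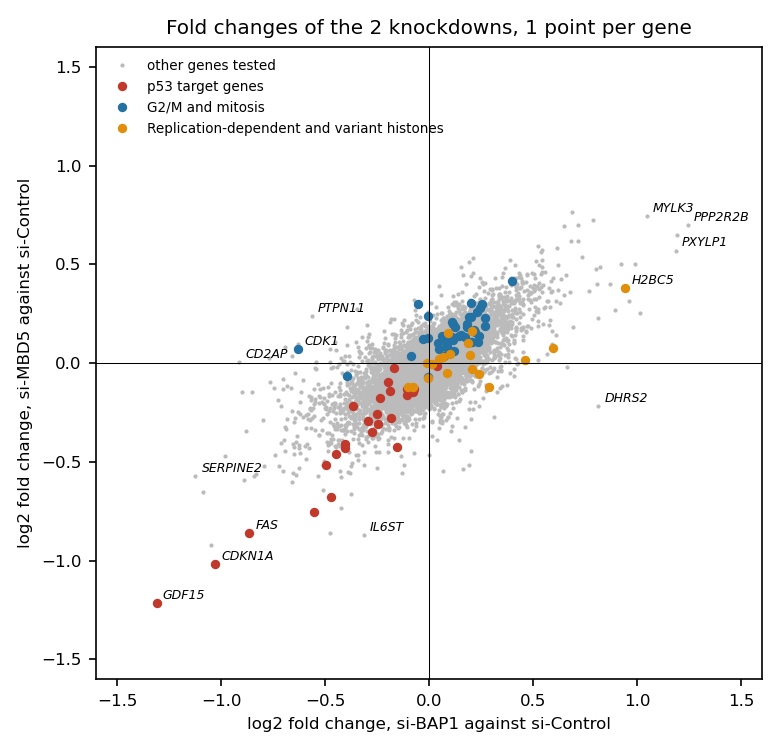
Log2 fold change of each of 12431 genes in si-BAP1 (horizontal) and si-MBD5 (vertical) against the same control arrays; p53 targets are red, G2/M genes blue and histone genes orange. Pearson r was 0.712, and GDF15 and CDKN1A lie at the lower left.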

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

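Probe sets with no symbol or several symbols lay outside the gene tests and were flagged because some passed the threshold. Their shares were not above those of probe sets with 1 symbol. Of 1320 probe sets with no gene symbol above the filter, 241 (18.3%) passed in si-BAP1 and 164 (12.4%) in si-MBD5 against control. Of 1066 with several symbols, 195 (18.3%) and 86 (8.07%) passed. Of 27190 with 1 symbol, 5548 (20.4%) and 3462 (12.7%) passed.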

How the results depend on the processing

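The fall of p53 targets kept its direction and its call in every setting in which lists were tested. In si-BAP1 the medians were -0.27 to -0.22 and camera adjusted p 1.9e-15 to 0.0296. In si-MBD5 they were -0.33 to -0.23 and 4.1e-21 to 0.0172. Lists were not tested with the mean of probe sets or without _x_at and _s_at probe sets. Nor were they tested with array weights, no intensity trend, robust variances or only the 2 groups compared. For named genes 6623 of 6877 repeats kept direction and side of the threshold, 251 lost the call and 3 reversed; for lists 488 of 543 kept it and 55 lost it. Except where a setting itself explains it, the cause was not tested.

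Array weights raised the counts to 4493 (2355 higher, 2138 lower) for si-BAP1, 3079 (1767 lower) for si-MBD5, 1119 higher between the knockdowns and 1118 lower in both. A minimum change of 1 log2 unit, a stricter rule, left 10 (5 higher, 5 lower), 2 (0 higher, 2 lower) and 1 (1 higher, 0 lower). The background covariate, chosen after the data were seen, gave 1952 genes between the knockdowns (1127 higher, 825 lower). An estimated correlation left 2, 2 and 0 lists in the 3 comparisons. Fry called 16, 11 and 1 lists, where the main test called 13, 11 and 5. With the replicate block, tried because arrays carry numbers, the counts were 2850, 1865 and 1115. Deviations of same-number arrays correlated at -0.433 to 0.480, and 7 of 18 best matches had the same number. Same-number arrays thus did not deviate together throughout, but a day or batch shared by some of them cannot be excluded.

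Leaving out 1 array in turn gave 1265 to 1970 genes for si-MBD5 (587 to 877 higher, 678 to 1198 lower), 720 to 1324 between the knockdowns (345 to 864 higher, 330 to 513 lower; 2 to 5 lists), and 441 to 679 lower in both. The covariance of the knockdowns was 0.0182 with a constant of 1, 0.00926 with 64, 0.0186 with none, 0.0104 without a filter, 0.0169 with a filter at the 60th percentile and 0.0114 with the mean of probe sets. With the mean of probe sets ASXL1 reversed to 0.0349 (si-BAP1) and 0.000682 (si-MBD5), and without _x_at and _s_at probe sets PCGF5 reversed to 0.0532 between the knockdowns. Weak signal limits the reading of MBD5. Changes near 0.1 log2 were rarely found in simulated data, where fewer genes changed than passed here, which makes the adjusted threshold stricter.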

Other observations

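The gene families and transcripts here were chosen after the data were seen, out of 19 families tested, as were the tests of control cultures, of background in the array deviations and of replicate numbers. Several moved the same way in both knockdowns with the preset correlation. In S100 calcium-binding proteins, 5 of 9 fell and 0 rose in si-BAP1 (camera adjusted p = 0.00408) and 4 fell and 0 rose in si-MBD5 cells (camera adjusted p = 9.6e-04), with S100A11 at log2 -0.30 and -0.24. In subunits of the V-ATPase, the proton pump of lysosomes, 5 of 16 fell and 0 rose in si-BAP1 (camera adjusted p = 0.0395) and 5 fell and 0 rose in si-MBD5 cells (camera adjusted p = 0.0210), with ATP6V0E1 at -0.30 and -0.30. In ABC transporters, 8 of 28 fell and 2 rose in si-BAP1 (camera adjusted p = 0.0395) and 6 fell and 1 rose in si-MBD5 cells (camera adjusted p = 0.0210): the drug and conjugate exporter ABCC3 had log2 -0.65 and -0.56, and the sterol exporters ABCA1 -0.64 and -0.56 and ABCG1 -0.51 and -0.64. In zinc finger ZNF genes, 60 of 314 rose and 13 fell in si-BAP1 (camera adjusted p = 0.0110) and 41 rose and 10 fell in si-MBD5 cells (camera adjusted p = 0.0220), with ZNF765 at 0.50 and 0.38. In kinesins, 10 of 36 rose and 3 fell in si-BAP1 (camera adjusted p = 0.0287) and 9 rose and 2 fell in si-MBD5 cells (camera adjusted p = 0.0119). With an estimated correlation none of the families passed, the lowest adjusted p being 0.154 in si-BAP1 and 0.166 in si-MBD5.

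Other probe sets of a gene held larger changes than the brightest one in some genes and smaller ones in others. A dimmer probe set of the actin-binding tropomyosin TPM4 rose from 365 to 728 in si-BAP1 (log2 0.97, adjusted p = 9.1e-08) and 751 in si-MBD5 (log2 1.01, adjusted p = 1.3e-07), while its brightest rose by 0.20 and 0.21. Of 7078 genes with at least 2 probe sets, 2531, 1767 and 1112 had any call in the 3 comparisons, and 32, 19 and 5 had calls in both directions.

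A first hypothesis was that the lower p53 targets reflect the arrays rather than the cells. With a background covariate the list kept a camera adjusted p of 3.40e-13 or less in both knockdowns (1.9e-15 to 0.0296 in si-BAP1 over the settings in which lists were tested), and 91.7% or more of its median stayed with any 1 control array left out, both against it. The list did not separate the knockdowns (camera adjusted p = 0.908), which is what a state of the 3 control cultures, or an effect of the control RNA, would also give, so that explanation stays open. Lower p53 output in both knockdowns may be biological, and further control cultures could tell.

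A second hypothesis was that the correlation of the knockdowns comes from their shared controls. The covariance of 0.0144 exceeded 2 times the highest of 100 simulations (0.00187), against shared measurement error as its only source, and r was 0.721 with the background covariate, against array background. A state shared by all 3 control arrays was not tested by this.

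Another hypothesis was that array background makes arrays of different groups deviate together from their group means. Component 1 of the deviations, 44.9% of their variance, followed the background of the 9 arrays with Pearson r of 0.918, as background would give. Without the 2 farthest arrays r was 0.869, and rho over all 9 was 0.833. Permutation gave p = 0.00142 for r and p = 0.00827 for rho. Those permutations moved the 9 deviations freely between groups, although deviations sum to 0 within each group. The p-values therefore ignore the grouping and may be too small. This relation was the only one tested. A day or batch marked by the replicate number would make same-number arrays deviate together. Their lowest correlation was -0.433, against a batch that dominates in all of them. Their highest was 0.480, also the highest of any pair between groups. With array background in the same deviations, a smaller batch cannot be excluded.

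Of the 10 ways to split the 6 arrays of a comparison, 1 gave as many genes, the real grouping, with 2917, 2024 and 1239 genes in the 3 comparisons; the highest other values were 0, 1 and 0. With 10 splits a share under 0.05 cannot be reached. Every other split mixed arrays of both groups, so real group differences entered its residual spread and lowered its count. The 0, 1 and 0 genes therefore do not measure the noise level.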
